A study of Acidomyces sp. 'richmondensis' with 12 samples.

How the data were processed

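The samples were 12 RNA-seq libraries of mycelia of Acidomyces richmondensis MEY-1, 3 from separate cultures in each of 4 groups: WT and ∆ArAceA, without and with 15 mM CuCl2 for 6 h. Groups and replicate numbers were taken from the sample titles and the genotype and treatment labels. Per the labels' protocols, total RNA was isolated with TRIzol and cleaned on columns, and libraries followed standard Illumina protocols; strand, read length and sequencing batches were not given in the sources used here.

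The authors deposited 1 table of FPKM per library and 1 table for the series, and the FPKM values in both were equal in all 12 libraries. The FPKM values are already scaled by transcript length and by library size, per the file headers. The authors' deposited series table also holds log2 ratios for 4 comparisons of groups, and a Q value for each ratio. Per the submitters' processing notes, HISAT2 2.1.0, RSEM 1.2.8 and DESeq2 were used, with no role, order or setting stated. The genome build and annotation were not given in the sources used here. Genes are listed by locus identifiers only, and the files do not pair these with gene names. Reads shared between near-identical genes were not analysed here, and a value of 0 means only that a gene was listed at 0. All columns of per-library values matched a sample, and 0 were left unmapped.

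Read counts were not used here, and the absolute depth of the libraries is unknown. FPKM steps of low genes gave relative depths: over 162 genes and 1070 values, 81.2% lay within 0.1 of a whole step, against 43.1% after random rescaling of each value, and the relative depths ran from 0.978 to 1.06. No library was a copy of another, since the highest share of equal values between any 2 libraries, over genes of at least 10 FPKM, was 0.225%.

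The planned test was a quasi-likelihood test on counts. Since the values were FPKM, the test planned for that unit was used instead, fixed before the data were examined: limma 3.58.1 in R 4.3.3, with mean-variance trend and robust moderation, on log2(FPKM + 1), for genes with an FPKM of at least 1 in at least 3 libraries. This left 8741 genes and dropped 1302. A single fit over the 4 groups gave 5 two-sided comparisons: copper in each genotype, ∆ArAceA against WT without and with copper, and the difference of the copper responses (the interaction). Benjamini-Hochberg adjustment ran over the 8741 genes in each comparison, and an adjusted p under 0.05 was called. A change of at least 2-fold means a called gene whose fitted log2 change was at least 1 in size. Fitted changes are on the log2(FPKM + 1) scale, which understates the change of genes of low level, whereas folds given beside FPKM are ratios of group means. No fold is given against a group listed at 0.

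Named genes followed a rule fixed before the data were examined. With no annotation, it took the 2 largest rises and the 2 largest falls of each comparison by fitted log2 change, among called genes with a mean of at least 5 FPKM in the higher group and with all 3 values of one group above all 3 of the other. The condition on separate values was dropped for the difference of responses. For single genes 10% of 3 against 3 splits separate fully by chance. Groups of genes were defined by their calls in the 5 comparisons. Functional gene lists, their set tests and the level of ArAceA had been planned, and were not run because the genes carry no names.

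The procedure was tested on simulated data. These took each gene's mean level and residual spread from the 12 libraries, with independent normal noise and no shift between libraries. They match what limma assumes, so they do not show the rate of false calls where libraries differ in scaling. For copper in WT, it recovered 84% of 100 genes changed 2-fold and 98% of 100 genes changed 4-fold, and called 9 of 8541 unchanged genes. For the difference of responses, the shares were 77% and 97%, with 10 of 8541 unchanged genes called. For copper in ∆ArAceA with no change simulated, 0 of 8741 genes were called.

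Alternatives fixed beforehand were a pseudocount of 0.1, no filter on low values, fits on only the groups compared, the replicate number as a block, other fold minimums for the genes raised in WT, and leaving out each library in turn. Scaling of the FPKM columns by the median of ratios or by the upper quartile, a filter asking for an FPKM of at least 1 in all 3 libraries of a group, and limma's test against a minimum fold of 2 were added after seeing the data. The fold changes of copper in WT and of ∆ArAceA without copper share the WT libraries, and their covariance was set against 20 simulations without effects.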

Results

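Transcript levels were measured by RNA sequencing in mycelia of Acidomyces richmondensis MEY-1, a fungus that grows in acid. A wild-type strain (WT) and a strain lacking the gene ArAceA (∆ArAceA) were each transferred to fresh medium without copper or with 15 mM CuCl2 and sampled after 6 h. The title of the study places the work among the determinants of copper resistance and names CRISPR/Cas9 as its editing tool. ArAceA shares its name with AceA of Aspergillus fumigatus, a transcription factor that responds to excess copper. The 12 libraries fell into 4 groups of 3 separate cultures each, and levels were given as FPKM (fragments per kilobase of transcript, scaled to library size) for 10043 genes. FPKM sums per library lay between 884111 and 926713. The number of reads behind each library was unknown, and the spacing of the lowest values put the relative depths of the libraries between 0.978 and 1.06.

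The 4 groups differed in the spread of their transcripts over genes. In WT without copper 577 ± 18.6 genes (mean ± SD, n = 3 cultures, here and for all group values that follow) were listed at 0, against 514 ± 10.97 in WT with copper, 471.0 ± 12.5 in ∆ArAceA without copper and 456 ± 5.51 in ∆ArAceA with copper. The 100 most abundant genes of a library held 37.1 ± 0.656% of its FPKM in WT and 37.2 ± 0.333% in WT with copper, but 32.2 ± 0.084% in ∆ArAceA and 34.5 ± 0.177% in ∆ArAceA with copper. Median FPKM was 14.4 ± 0.359 and 14.2 ± 0.119 in WT without and with copper, and 16.7 ± 0.042 and 16.0 ± 0.331 in ∆ArAceA. Replicate libraries correlated at r = 0.993 to 0.996 across genes on the log2(FPKM + 1) scale. Libraries of WT without and with copper correlated at 0.984 to 0.988, and those of ∆ArAceA without and with copper at 0.962 to 0.966. Genes are not independent replicates, so these coefficients describe the libraries only.

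**Figure D1:**
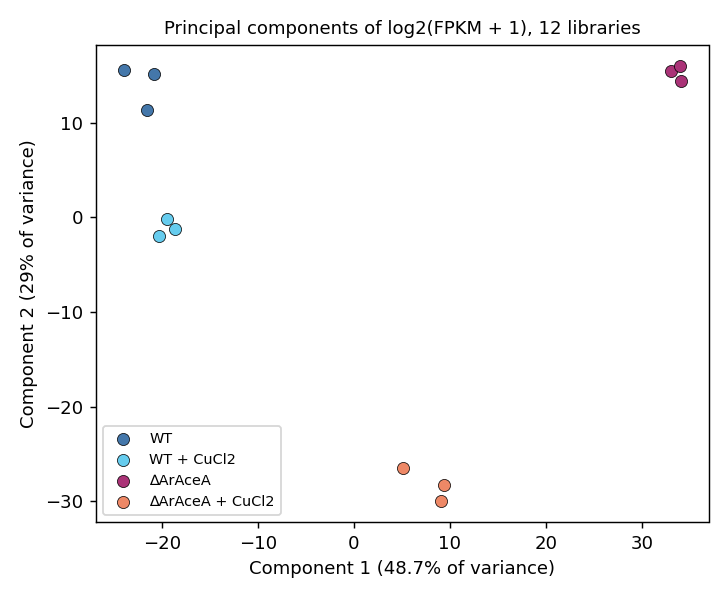
Each point is 1 of the 12 libraries, placed by its scores on components 1 (horizontal) and 2 (vertical) of log2(FPKM + 1) over 8741 genes, which held 48.7% and 29% of the variance. The 3 libraries of each group lie together, with the 6 WT libraries between -23.98 and -18.58 on component 1, ∆ArAceA without copper between 33.1 and 34.1, and ∆ArAceA with copper between 5.15 and 9.44.

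The genes carry locus identifiers that the files do not pair with names. The level of ArAceA itself was therefore not analysed here, and the genotypes were taken from the labels alone. Across all 10043 genes, 0 had an FPKM of at least 1 in all 6 WT libraries and were listed at 0 in all 6 ∆ArAceA libraries. The opposite held for 3 genes, listed at 0 in all 6 WT libraries and at 1 FPKM or more in all 6 ∆ArAceA libraries. In 10 genes every ∆ArAceA library lay more than 2-fold below the lowest WT library, itself of at least 1 FPKM, and in 76 genes every WT library lay as far below the lowest ∆ArAceA library.

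Copper changed a small set of genes strongly in WT. At an adjusted p under 0.05, 1867 of the 8741 genes tested responded to 6 h of CuCl2, 929 of them upwards and 938 downwards, and 105 rose and 16 fell by at least 2-fold. The typical gene of the 105 went from 4.31 FPKM without copper to 14.8 FPKM with it, and their median log2 change was 1.403. The largest rise was in M433DRAFT_310551, from 15.6 ± 0.345 to 447 ± 35.3 FPKM, a 28.7-fold difference between means. M433DRAFT_154429 rose 12.9-fold, from 3.48 ± 0.432 to 44.99 ± 4.28 FPKM. The largest falls were in genes that every copper library listed at 0. M433DRAFT_446038 had 11.2, 10.8 and 9.72 FPKM in the 3 WT libraries without copper, and M433DRAFT_966 had 6.27, 7.87 and 6.21 FPKM. Both were also at 0 in all 3 ∆ArAceA libraries with copper.

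The test was limma's moderated test on log2(FPKM + 1), and the adjusted p of the 4 genes ranged from 9.3e-14 for M433DRAFT_310551 to 5.42e-09 for M433DRAFT_446038. The fitted log2 changes were 4.76 (SE 0.074) for M433DRAFT_310551 and 3.36 (SE 0.078) for M433DRAFT_154429. Tested against a minimum change of 2-fold, 41 genes passed, 36 higher and 5 lower, and with a pseudocount of 0.1 in place of 1 the genes of at least 2-fold were 161 higher and 26 lower. The split of all calls depended on the scaling of the libraries, with 49.8% higher in the FPKM as deposited and 60.3% higher (1131 against 746) after upper-quartile scaling.

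In ∆ArAceA copper changed more genes by the same test, and the strong changes were mostly falls. In ∆ArAceA 4915 genes responded, 2159 upwards and 2756 downwards, and 167 rose while 368 fell by at least 2-fold. The 368 lowered genes went from a median of 28.3 FPKM to 9.66 FPKM, whereas in WT the same genes had medians of 10.0 FPKM without copper and 9.53 FPKM with copper, and 260 of them were not called there. By the test of the difference between genotypes, 341 of the 368 responded more negatively in ∆ArAceA, as did 2236 of all 8741 genes. Choosing genes by their fall in ∆ArAceA favours such a difference, so the count of 341 is no separate evidence. The 167 raised genes went from a median of 5.59 to 19.7 FPKM, and 107 of them were also called higher with copper in WT. M433DRAFT_154429 rose 37.4-fold, from 5.59 ± 0.232 to 209 ± 5.98 FPKM, and M433DRAFT_146212 rose 40.9-fold, from 0.98 ± 0.114 to 40.1 ± 2.79 FPKM. In WT M433DRAFT_146212 rose 5.73-fold, from 1.03 ± 0.104 to 5.92 ± 0.577 FPKM. M433DRAFT_387617 fell from 235 ± 49.8 to 6.82 ± 3.04 FPKM. M433DRAFT_6878, one of the abundant transcripts, fell from 930 ± 87.9 FPKM to 5.09, 209 and 12 FPKM in the 3 libraries with copper. In WT M433DRAFT_387617 went from 144 ± 26.2 to 70.2 ± 36.3 FPKM and M433DRAFT_6878 from 2236 ± 665 to 1139 ± 256 FPKM, neither called. The difference of responses was called for M433DRAFT_387617 (limma adjusted p = 0.00114) but not for M433DRAFT_6878 (0.0559).

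By limma the adjusted p was 9.41e-14 for M433DRAFT_154429, 1.56e-12 for M433DRAFT_146212, 1.31e-05 for M433DRAFT_387617 and 0.00389 for M433DRAFT_6878. Against a minimum change of 2-fold, 188 genes passed, 66 higher and 122 lower, and M433DRAFT_6878 was not among them. The share of higher calls was 43.9% in the FPKM as deposited and 54.7% (2767 against 2287) after upper-quartile scaling, while the 2-fold falls still outnumbered the 2-fold rises, at 308 against 178.

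The copper responses of the genotypes overlapped in part. Genes raised in both numbered 400, against 229.5 for independent lists of these sizes (one-sided Fisher's exact test, p = 7.74e-39, adjusted p = 3.1e-38 over 4 tests), and genes lowered in both numbered 388 against 295.7 (p = 1.11e-11, adjusted p = 2.22e-11). The balance of raised and lowered genes depended on the scaling, with 468 and 360 after median-of-ratios scaling and 539 and 269 after upper-quartile scaling. Genes called in opposite directions were 251 raised in WT and lowered in ∆ArAceA, against 292.9, and 203 the other way, against 231.7. Among the strong responders, 55 genes rose by at least 2-fold in both genotypes, where independent lists would share 2. These comparisons share no library, but the single fit gave both the same estimate of each gene's spread. Genes of small spread are called more readily in both, in any direction, so independent lists are not an exact reference. Fisher's test treats genes as independent, which they are not, so its p-values do not measure the spread between cultures. Across all tested genes the log2 changes correlated at r = 0.289 (Spearman's rho = 0.111), with genes not independent of one another.

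The genes that copper induced in WT divided into 3 classes by the test of the difference between genotypes. Of the 105 genes, 54 responded less in ∆ArAceA, 20 responded more and 31 had no called difference. The 54 genes had a median log2 change of 1.42 in WT and 0.31 in ∆ArAceA, and 25 of them were not called higher with copper in ∆ArAceA. In the cultures without copper their median level was higher in ∆ArAceA, at 16.0 FPKM against 7.07 FPKM in WT, and with copper the medians were 21.4 and 19.5 FPKM. Gene by gene, the median log2 difference of ∆ArAceA from WT with copper was -0.32, with 26 of the 54 called lower, 9 higher and 19 not called. The 20 genes with a larger response rose from 3.75 to 16.2 FPKM in WT and from 5.99 to 49.7 FPKM in ∆ArAceA, taking medians over genes. The 31 genes without a called difference rose with median log2 changes of 1.44 in WT and 1.37 in ∆ArAceA. M433DRAFT_310551, the gene most raised in WT, stood at 13.8 ± 0.873 FPKM without copper and 11.9 ± 1.15 FPKM with copper in ∆ArAceA. M433DRAFT_154429 showed the reverse order, with its response larger in ∆ArAceA by 1.63 on the log2 scale (SE 0.11, limma adjusted p = 2.61e-07).

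**Figure D2:**
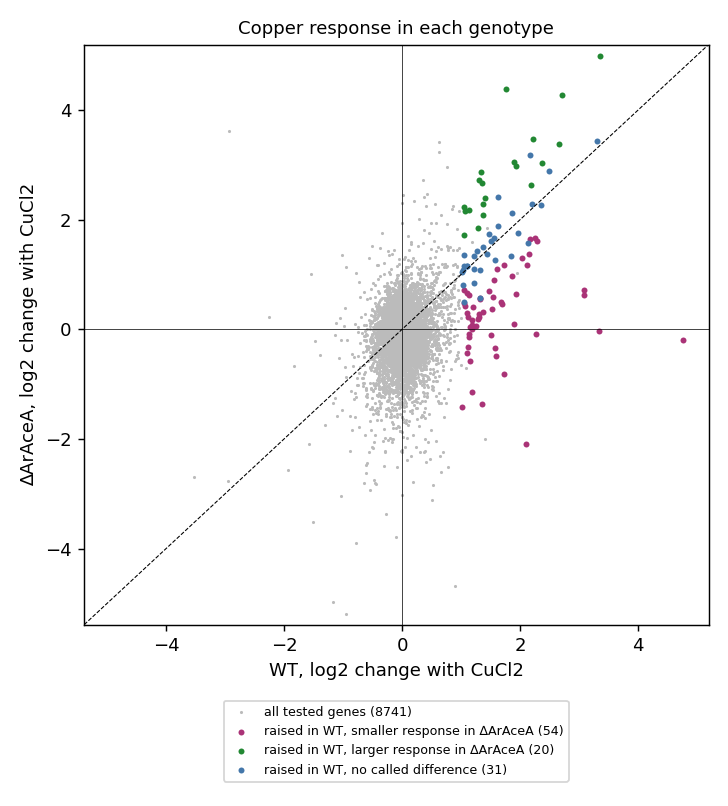
Each point is 1 of 8741 tested genes, with its fitted log2 change with CuCl2 in WT (horizontal) and in ∆ArAceA (vertical); the dashed line marks equal changes. Of the 105 genes raised at least 2-fold in WT, the 54 with a smaller response in ∆ArAceA lie below the line, the 20 with a larger response above it and the 31 with no called difference near it.

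Over all genes, the copper response differed between genotypes in 4006, with 1770 more positive and 2236 more negative in ∆ArAceA (limma, adjusted p under 0.05), and the difference was at least 2-fold in 92 and 417 genes. The 417 genes had median FPKM of 6.61 and 7.57 in WT without and with copper, and 19.3 and 7.46 in ∆ArAceA. Without copper 378 of them were called higher in ∆ArAceA, and with copper 122 were called higher, 121 lower and 174 neither. The even split with copper depended on the scaling. It was 95 higher and 146 lower after median-of-ratios scaling, and 103 and 137 after upper-quartile scaling. Genes chosen by a negative difference of responses tend by that choice to be higher in ∆ArAceA without copper or lower with it. M433DRAFT_63521 had the most negative difference, at 3.94 ± 0.395 and 8.19 ± 0.384 FPKM in WT and 214 ± 9.80 and 7.50 ± 1.48 FPKM in ∆ArAceA. The 92 genes had medians of 8.75 and 8.98 FPKM in WT, and 6.17 and 20.9 FPKM in ∆ArAceA. M433DRAFT_357512 belonged to them, at 1.39 ± 0.214 and 2.75 ± 0.855 FPKM in WT and 2.46 ± 0.445 and 35.8 ± 4.83 FPKM in ∆ArAceA. M433DRAFT_131828 moved in opposite directions, with 10.3, 12.6 and 8.15 FPKM in WT, 0.57, 1.01 and 0 in WT with copper, 0 in all 3 ∆ArAceA libraries and 7.40, 16.5 and 11.5 FPKM in ∆ArAceA with copper.

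The fitted differences of response were 6.55 (SE 0.393) for M433DRAFT_131828, 2.79 (SE 0.231) for M433DRAFT_357512, -5.57 (SE 0.143) for M433DRAFT_63521 and -4.96 (SE 0.105) for M433DRAFT_310551, with limma adjusted p of 3.05e-07, 1.36e-06, 2.06e-11 and 4.89e-12. A minimum difference of 2-fold was passed by 86 genes, 11 more positive and 75 more negative in ∆ArAceA. The majority among all calls turned with the scaling, at 1979 more positive and 2140 more negative after median-of-ratios scaling and 2121 and 2021 after upper-quartile scaling, while differences of at least 2-fold were 100 and 370 after the latter.

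**Figure D3:**
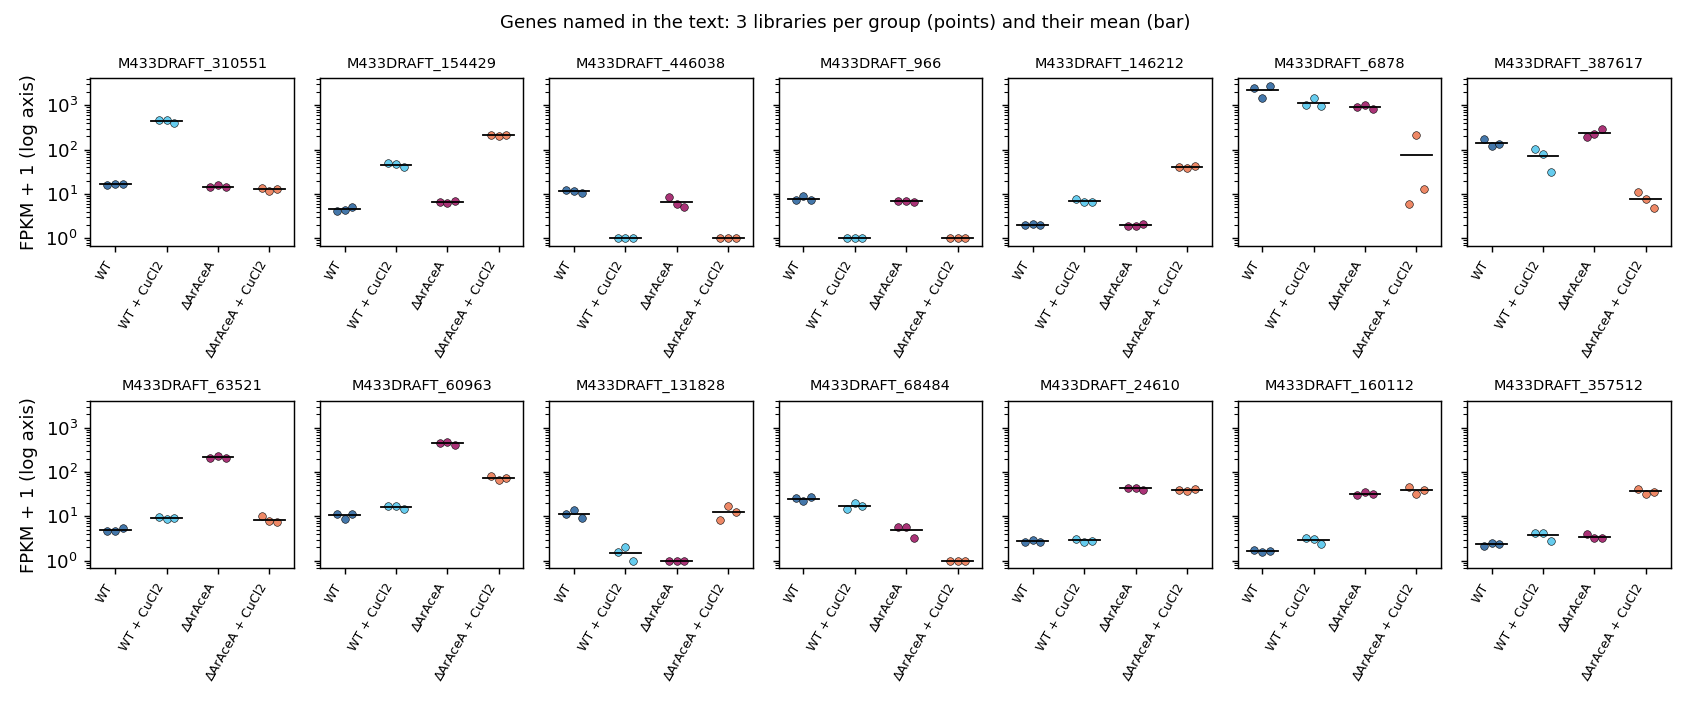
FPKM plus 1 on a log axis for the 14 genes named by identifier, with each of the 3 libraries of a group as a point and their mean as a bar. M433DRAFT_310551 reached 407 to 471 FPKM in WT with copper only, and M433DRAFT_63521 reached 206 to 225 FPKM in ∆ArAceA without copper only.

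∆ArAceA differed from WT in many genes even without copper. Between the strains without copper 5133 genes differed, and 698 genes were higher and 67 lower by at least 2-fold in ∆ArAceA. The 698 genes were mostly of low to middling level in WT, with a median of 4.76 FPKM against 16.5 FPKM in ∆ArAceA. M433DRAFT_63521 was 54.4-fold higher in ∆ArAceA, as given above, and M433DRAFT_60963 was 46.5-fold higher, at 442 ± 38.3 against 9.51 ± 1.53 FPKM. M433DRAFT_131828 was listed at 0 in all 3 ∆ArAceA libraries, and M433DRAFT_68484 was 6.204-fold lower, at 3.88 ± 1.44 against 24.1 ± 2.12 FPKM. The 67 lowered genes had a median of 25.3 FPKM in WT and 8.46 FPKM in ∆ArAceA.

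The limma adjusted p was 1.85e-13 for M433DRAFT_63521, 2.4e-12 for M433DRAFT_60963, 5.09e-07 for M433DRAFT_131828 and 2.56e-07 for M433DRAFT_68484. The median gene lay 0.12 higher in ∆ArAceA on the log2 scale, and the split of calls depended on the scaling: 3564 were higher and 1569 lower (69.4% higher) in the FPKM as deposited, and 2704 and 2763 (49.5%) relative to the median gene, by median-of-ratios scaling. On that scaling 543 genes were higher and 85 lower by at least 2-fold, and a minimum change of 2-fold was passed by 318 higher and 21 lower genes in the FPKM as deposited.

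With copper fewer genes differed strongly between the genotypes. In copper 4086 genes differed, and 238 were higher and 114 lower by at least 2-fold in ∆ArAceA. The 698 genes at least 2-fold higher in ∆ArAceA without copper had a median log2 difference of 1.34 there and 0.47 with copper. The test of the difference called the decrease in 587. With copper 141 were still at least 2-fold higher, and 473 were called higher and 26 lower (400 and 38 after median-of-ratios scaling). The median FPKM of the 698 genes moved from 16.5 to 9.05 with copper in ∆ArAceA, and from 4.76 to 5.71 in WT. Of the 368 genes that copper lowered at least 2-fold in ∆ArAceA, 220 were among these 698, against 29.4 for independent lists. Both lists used the ∆ArAceA libraries without copper, so part of this excess can come from chance values in them. In 20 simulations without any effect 0 genes were shared, but hardly any gene is called there, so that value does not measure the part. M433DRAFT_24610 and M433DRAFT_160112 led the genes higher with copper, at 1.87 ± 0.227 and 1.92 ± 0.469 FPKM in WT with copper and 38.6 ± 2.78 and 38.8 ± 7.05 FPKM in ∆ArAceA with copper, 20.6-fold and 20.2-fold higher. Without copper they were 24.2-fold and 45.3-fold higher.

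The largest fitted falls in ∆ArAceA with copper were in M433DRAFT_310551, 37.7-fold lower than in WT by the means, and M433DRAFT_6878, 15.1-fold lower, at 1139 ± 256 FPKM in WT against the 5.09 to 209 FPKM given above. Their order by fitted change turned when single libraries were left out. With all libraries M433DRAFT_6878 was at -5.46 and M433DRAFT_310551 at -5.12. They were at -4.43 and -5.18 without ∆ArAceA with copper replicate 1, and at -4.97 and -5.14 without replicate 3. Without replicate 2, the library at 209 FPKM, they were at -6.98 and -5.05. Of the 114 lowered genes, 92 were not 2-fold lower without copper. Those 92 had medians of 41.1 and 52.5 FPKM in WT without and with copper, and 35.9 and 14.5 FPKM in ∆ArAceA. Another 22 were 2-fold lower in both conditions, with medians of 36.5 FPKM in WT and 10.0 FPKM in ∆ArAceA without copper. M433DRAFT_68484 was among the lowered genes, at 16.1 ± 2.61 FPKM in WT and listed at 0 in all 3 ∆ArAceA libraries with copper.

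The limma adjusted p was 3.65e-12 for M433DRAFT_24610, 3.92e-10 for M433DRAFT_160112, 0.00398 for M433DRAFT_6878 and 3.51e-14 for M433DRAFT_310551. The median gene was again higher in ∆ArAceA, by 0.12 on the log2 scale. The calls were 3092 higher and 994 lower (75.7% higher) in the FPKM as deposited, 1896 and 1877 (50.3%) by median-of-ratios scaling, with 181 and 145 of at least 2-fold, and 2134 and 1630 (56.7%) by upper-quartile scaling. Against a minimum change of 2-fold 89 higher and 27 lower genes passed, without M433DRAFT_6878, and with a pseudocount of 0.1 the genes at least 2-fold higher in both conditions were 226 in place of 141. Across genes the genotype differences without and with copper, which share no library, correlated at r = 0.451 (Spearman's rho = 0.371).

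**Figure D4:**
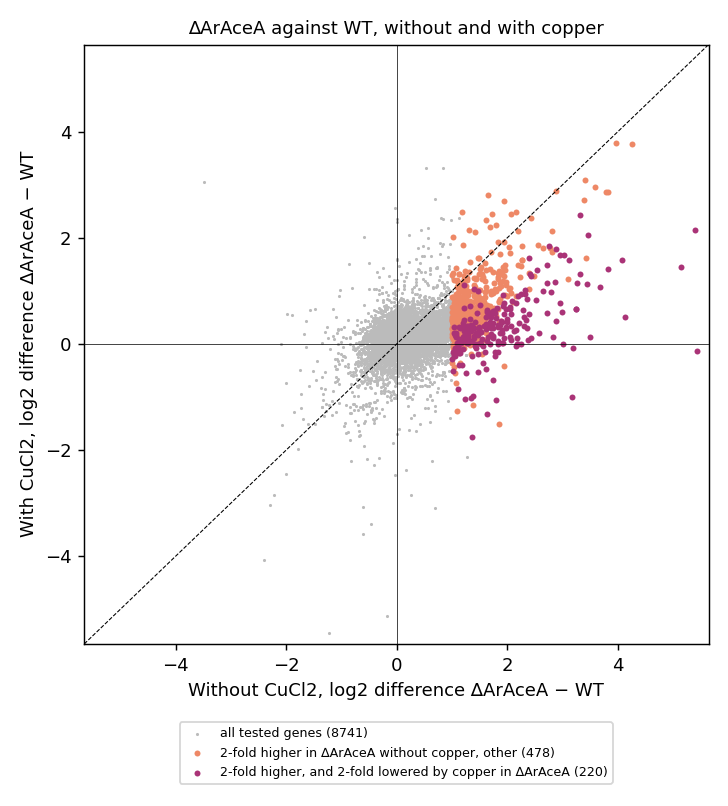
Each point is 1 of 8741 tested genes, with its fitted log2 difference of ∆ArAceA from WT without copper (horizontal) and with copper (vertical); the dashed line marks equal differences. Among the 698 genes at least 2-fold higher without copper, the 220 that copper lowered at least 2-fold in ∆ArAceA have a median of 1.70 without copper and 0.27 with copper.

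The authors' deposited table gave its own log2 ratios and Q values for the 4 comparisons between groups. At Q under 0.05 the authors' deposited table listed 1147 genes for copper in WT, 4672 for copper in ∆ArAceA, 4745 for ∆ArAceA against WT without copper and 3251 with copper. Of the limma calls, 1093, 4272, 3802 and 2440 were also under that Q in the authors' deposited table, in the same order. These were 58.5%, 86.9%, 74.1% and 59.7% of the limma calls. For ∆ArAceA against WT the limma log2 difference exceeded the deposited one by a median of 0.145 without copper and 0.126 with copper. For the genotype comparisons the authors' deposited table had 49.8% of its listed genes higher without copper and 47.5% with copper. Changes of at least 2-fold in the authors' deposited table were 809 higher and 102 lower for ∆ArAceA without copper, and 248 and 164 with copper. For copper they were 220 higher and 432 lower in ∆ArAceA, and 121 and 17 in WT.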

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

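Of the tests in this part, the one that uses median-of-ratios scaling and the simulation of equal copper responses were chosen after the results were seen. The copper response differed between genotypes in 4006 genes by the test of the difference itself. In 100 drawn assignments of the 12 libraries to 4 groups, the real one included, 1 gave as many genes, and the highest of the others gave 3088. Such draws ask only whether the 12 libraries are interchangeable. The copper and genotype differences alone already make them unlike, so the draws cannot test the difference of responses. The 4 comparisons of 3 libraries with 3 allow 10 splits each, so the share of splits that give as many genes can never fall under 0.1. Fitted on the 6 libraries alone, copper in WT gave 1255 genes against at most 0 in another split, copper in ∆ArAceA 5116 against 1, ∆ArAceA without copper 4728 against 0 and ∆ArAceA with copper 4227 against 0. In each of these, 1 of the 10 splits, the real one, gave as many.

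The 2 largest differences in each direction, by the rule for named genes, were M433DRAFT_131828 (6.55 on the log2 scale, lowered by copper in WT and raised in ∆ArAceA), M433DRAFT_357512 (2.79) upwards, and M433DRAFT_63521 (-5.57) and M433DRAFT_310551 (-4.96) downwards. M433DRAFT_131828 was listed at 0 in 4 of the 12 libraries, so the size of its difference depends on the pseudocount, and it was 11.4 with a pseudocount of 0.1.

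Of 105 genes raised at least 2-fold by copper in WT, 54 responded less in ∆ArAceA. Choosing genes by their response in WT favours a smaller response elsewhere, but 20 simulations with equal responses in both genotypes gave 0 to 10 such genes (mean 4.7), against the 54 seen. Each count took genes with an unadjusted p of at most 0.0229, the largest of a called difference. The simulations speak only to that choice of genes. Over all tested genes, 2236 of 8741 responded more negatively in ∆ArAceA, so independent lists would share 26.9 of the 105 genes. A lower effective dose of copper in the ∆ArAceA cultures would have lowered the responses together, if each rises with dose, which was not tested. Of the 105 genes, 20 (19%) responded more in ∆ArAceA, against 21.3 for independent lists. The number was 19 of 161 with a pseudocount of 0.1 and 2 of 36 against a minimum fold of 2. The value for independent lists rests on all genes with a larger response, so it measures no dose effect. A lower dose alone would leave no gene with a larger response, under that assumption. The 20 genes had a median log2 change of 1.39 in WT and 2.69 in ∆ArAceA, though their choice favours this order. Over all genes, 167 rose and 368 fell by at least 2-fold in ∆ArAceA, against 105 and 16 in WT. These values argue against a lower dose as the only difference, for the genes they cover. A part for dose in the 54 stays open. A dependence of part of the copper response on ArAceA is a candidate explanation and remains a hypothesis, since the level of ArAceA was not analysed here. Of the 54 genes, 42 were higher in ∆ArAceA than in WT without copper and 26 lower with copper, but the choice of the genes used the same libraries and favours both, so these counts are no separate evidence.

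The 698 genes at least 2-fold higher in ∆ArAceA without copper had a median log2 difference of 0.47 with copper. In 20 simulations with equal genotype differences in both conditions the lowest median was 1.31, so the choice of genes does not account for the drop. After median-of-ratios scaling the median of the same 698 genes with copper was 0.301 of that without, at 0.37 against 1.22. A single factor per library therefore does not account for the drop either, but it cannot remove a shift that depends on level. The lower quartile of FPKM in the ∆ArAceA libraries was 3.34 to 3.365 without copper and 2.78 to 3 with copper. The difference shrank rather than vanished, since 473 of the 698 were still called higher in ∆ArAceA with copper, against 246.9 for independent lists. After median-of-ratios scaling 400 of the 698 were called higher. That these genes differ less with copper may be a property of the strain, and a different growth state of the ∆ArAceA cultures at sampling stays open as untested.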

How the results depend on the processing

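The median-of-ratios and upper-quartile scalings, the filter on all 3 libraries of a group and the test against a minimum fold of 2 were chosen after seeing the data. A minimum fold of 2 moved every count, by its construction: 41 genes for copper in WT, 188 for copper in ∆ArAceA, 339 for ∆ArAceA against WT without copper, 116 with copper, 86 for the difference of responses, 21 changed alike by copper in both genotypes, and 5 of 36 genes raised in WT with a smaller response in ∆ArAceA. M433DRAFT_6878 then no longer passed for copper in ∆ArAceA or for ∆ArAceA with copper. With no minimum fold for genes raised in WT, 490 of 929 had a smaller response, and with a minimum log2 fold of 2, 12 of 24. With a pseudocount of 0.1, genes of at least 2-fold numbered 161 raised (105 with a pseudocount of 1) and 26 lowered (16) by copper in WT, and 226 (141) were higher in ∆ArAceA in both conditions, since a smaller pseudocount shrinks the changes of low genes less. No other alternative moved these 7 counts by over 1.5 times. The genes behind the counts moved more in the genotype comparisons. Median-of-ratios scaling kept 4273 of 5133 calls without copper and 2890 of 4086 with copper, in the same direction. It kept 1788 of 1867 for copper in WT, 4713 of 4915 for copper in ∆ArAceA and 3893 of 4006 for the difference. Under all alternatives but the minimum fold of 2, every named gene kept its direction and its call in the comparison for which it was named. Its calls in other comparisons were not followed. Leaving out 1 library gave 1310 to 1802 genes for copper in WT, 4425 to 5030 for copper in ∆ArAceA, 4677 to 5119 for ∆ArAceA without copper, 3409 to 4272 with copper, 3604 to 3942 for the difference, 613 to 797 changed alike, and 48 to 61 with a smaller response. Replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.02 on average over 18 pairs, 0 of them above 0.1, and a library correlated best with its own number in 16 of 36 cases. With the number as a block the calls were 1621, 4733, 4985, 3882 and 3791 in the order above. Alternatives fixed beforehand that need counts or gene names (another count test, count scalings and filters, gene set tests) were not run. Depth is unknown, so what low coverage hides among the 1302 genes below the filter was not assessed.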

Other observations

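The tests of scaling in the last paragraph of this part were chosen after the result was seen. Copper raised 57 genes by at least 2-fold in ∆ArAceA that were not called in WT. These genes had medians of 4.90 and 5.52 FPKM in WT and 2.76 and 10.1 FPKM in ∆ArAceA without and with copper, and the difference of responses was called in 49 of them. A set of 43 genes, 19 of them among the 57, was at least 2-fold higher in ∆ArAceA with copper and not called higher without it, with medians of 5.54 FPKM in WT and 16.7 FPKM in ∆ArAceA under copper. Copper raised 38 of the 43 in ∆ArAceA and 9 in WT. The choice of the 57 and of the 43 used the same libraries as these counts. It favours their overlap, a rise in ∆ArAceA and a called difference, so the counts only describe the sets.

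Some genes induced by copper in WT were also high in ∆ArAceA without it. Of the 105 genes, 26 were at least 2-fold higher in ∆ArAceA than in WT without copper, where independent lists would share 8.4. Both lists used the WT libraries without copper, so part of the excess can come from them, and simulations without effects call too few genes to measure it. Their medians were 6.61 and 18.7 FPKM in WT without and with copper, and 19.0 and 30.8 FPKM in ∆ArAceA. Across all tested genes, the changes with copper in WT and the differences of ∆ArAceA from WT without copper had a covariance of 0.0482. It was at most 0.0105 in 20 simulations with no effects and the same shared WT libraries, and the excess over the simulated mean was 0.0396. The correlation was 0.267, against a simulated mean of 0.503.

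More genes were higher than lower in ∆ArAceA without copper. For the split of all calls, scaling and a real shift cannot be told apart: 49.5% of calls were higher after median-of-ratios scaling, and 50.3% (2732 against 2697) after upper-quartile scaling. Both scalings follow the bulk of the genes and brought the median log2 difference to -0.01, so either would also remove a real shift of most genes. For changes of at least 2-fold the centring leaves most of the excess, since 86.5% were still higher. A single factor per library therefore does not account for it, but such a factor cannot remove a shift that depends on level. The lower quartile of FPKM was 2.24 to 2.255 in the WT libraries without copper and 3.34 to 3.365 in those of ∆ArAceA. A technical shift of low genes was not excluded. Whether the remaining excess is biological was not tested further.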
